A study of Caenorhabditis elegans with 10 samples.

How the data were processed

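RNA was measured by sequencing in 10 libraries of Caenorhabditis elegans embryos, collected 3 hours after egg preparation. Per the labels, the libraries form 5 groups of 2. Wild-type (N2) embryos of parents grown on 50 mM NaCl were placed on 50 mM or 500 mM NaCl, and so were embryos of lin-45(n2018), a mutant of the RAF kinase that acts between RAS and ERK. In the fifth group, N2 parents grew on 300 mM NaCl and their embryos were placed on 500 mM. The groups are called N2 50 mM, lin-45 50 mM, N2 500 mM, lin-45 500 mM and N2 300-500 mM, and the last is called preconditioned. Per the labels' protocols, RNA was extracted after bead lysis and treated with DNase, polyadenylated RNA was selected, and TruSeq libraries were sequenced as read pairs on a NextSeq.

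The submitters' processing notes name BWA 0.6.1, RSEM 1.2.15, bedtools 2.25.0, DESeq 1.10.1 and the genome build ce10. The role and order of these tools, the gene annotation version and the strandedness of counting are not given in the sources used here. The deposited table holds 45461 genes, of which 20389 are protein-coding, 22753 are noncoding RNA genes and 1431 are pseudogenes. For each library the authors give an RSEM expected count, which is not normalized. The authors also give a deposited FPKM value, scaled by transcript length and library size. The deposited log2 values equal log2(FPKM + 1), with a largest difference of 5.15e-14 and a pseudocount of 1. Per the file headers, 2 further columns hold the mean and the variance of the log2 values over the libraries. FPKM, log2, mean and variance columns were checked and not used for tests. Of the nonzero expected counts, 59.9% are whole numbers, and all were rounded before testing. Names that were missing or shared by several genes were replaced by the sequence name for 8 genes.

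Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with at least 1 CPM (counts scaled to a common library size) in at least 2 libraries were kept, which left 14802 genes holding at least 99.89% of the counts of every library. A total of 23418 genes had no count in any library. Libraries were scaled by trimmed mean of M values (TMM), with factors from 0.923 to 1.083. All CPM values are TMM-scaled. A single quasi-likelihood model with a mean for each of the 5 groups was fitted to all 10 libraries, because 2 libraries per group give too few residual degrees of freedom alone. The fit had 5 residual and a median of 3.65 prior degrees of freedom. Its common dispersion of 0.0173 is a coefficient of variation of 13.1%. Each of the 7 comparisons was tested with edgeR's two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The comparison of salt responses is an interaction contrast, the salt effect in lin-45 minus the salt effect in N2. Errors given with log2 fold changes are standard errors (SE) of the fit, and errors given with CPM are standard deviations (SD) of 2 libraries.

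An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so no gene could pass such a test alone, and every call rests on the spread pooled across genes and groups. The labels do not say whether replicate libraries come from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

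The choice of tests, filters, lists, named genes and most alternatives was made before the data were examined. Genes are named by a rule. gpdh-1, gpdh-2 and lin-45 are named in every comparison. The 8 highest and 8 lowest fold changes qualify among genes past the threshold with a mean of at least 10 CPM in the higher group and every library of the higher group above every library of the lower. For the interaction only the threshold and the CPM minimum apply. Up to 4 members of each list with the smallest p-values past the threshold complete the rule. Names outside it are said to be chosen after their values were seen.

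Of the 33 gene lists written from general knowledge, 32 had at least 3 measured members and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. The 224 tests were adjusted together by Benjamini-Hochberg. Each was repeated with a correlation estimated from the residuals. With the preset correlation 78 tests passed, and with the estimated correlation 0 passed. The lowest adjusted p with an estimated correlation was 0.448, and that value is given beside each call. The number of members past the threshold is given after adjustment over all genes and after adjustment over the list alone. A total of 5 listed names did not match the table.

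A fold against a group without any count is a lower bound, computed with 3 counts over the group. With 1 to 3 counts the ratio of summed counts is given, for some genes with an exact 95% interval. Such intervals and bounds cover counting error only. Identical counts were found for 63 genes, and 3226 tested genes overlap another gene model, so that reads of these genes can be shared. Coordinates are those of the deposited table, on ce10.

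Correlations between the fold changes of comparisons are computed across genes, which are not independent replicates. Beside them stand values from 50 simulations in which no group differed, with the same shared libraries, and the overlaps that independent calls would give. The simulations drew each gene independently with the same dispersion in all groups, so their ranges leave out variation that genes share. Correlations with preconditioning are therefore also given with a jackknife SE over the 10 libraries.

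The test was checked on simulated negative binomial counts for the preconditioned comparison with 14661 genes. edgeR recovered 27.1% of simulated 1.5-fold changes, 70% of 2-fold and 95% of 4-fold changes. Of its 139 calls 14 were false (10.1%), above the nominal rate. DESeq2 gave 20.2% false calls and limma-voom 12.2%. Counts of called genes are therefore read as approximate.

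Alternatives were DESeq2 1.42.0, limma-voom, RLE (the DESeq2 size factors within edgeR) and upper-quartile factors, no filter, a minimum of 5 CPM, only the groups compared, the replicate number as a block, each library left out, and a fold of at least 2. Total-count scaling and correlations over the most abundant genes only were added after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.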

Results

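RNA-seq counts were obtained for 10 libraries of C. elegans embryos in 5 groups of 2, with 22138098 to 34585489 counts per library. Replicates 1 and 2 held 22138098 and 30985335 counts in N2 50 mM, 23498074 and 30356117 in lin-45 50 mM, 30707517 and 23611283 in N2 500 mM, 32066595 and 29606281 in lin-45 500 mM, and 34585489 and 33832939 in the preconditioned N2 300-500 mM group. Each library had counts for 18871 to 19671 genes. Protein-coding genes took 98.5% to 98.9% of the counts, and the 10 most abundant genes 3.51% to 4.58%. Over the 14802 tested genes, the pooled coefficient of variation between replicates was 13.1%.

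The embryo's salt level separated the libraries most. The root mean square log2 difference per gene between groups was 1.38 for N2 on 500 against 50 mM and 1.52 for lin-45 on 500 against 50 mM. It was 0.923 between the strains on 50 mM, 0.505 between the strains on 500 mM and 0.662 between preconditioned and other N2 embryos on 500 mM. Within groups it was 0.325 in N2 50 mM, 0.424 in lin-45 50 mM, 0.323 in N2 500 mM, 0.269 in lin-45 500 mM and 0.587 in N2 300-500 mM. The preconditioned pair was therefore the least alike, with 794 genes at least 2-fold apart, against 694 in lin-45 50 mM and 127 in lin-45 500 mM.

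**Figure D1:**
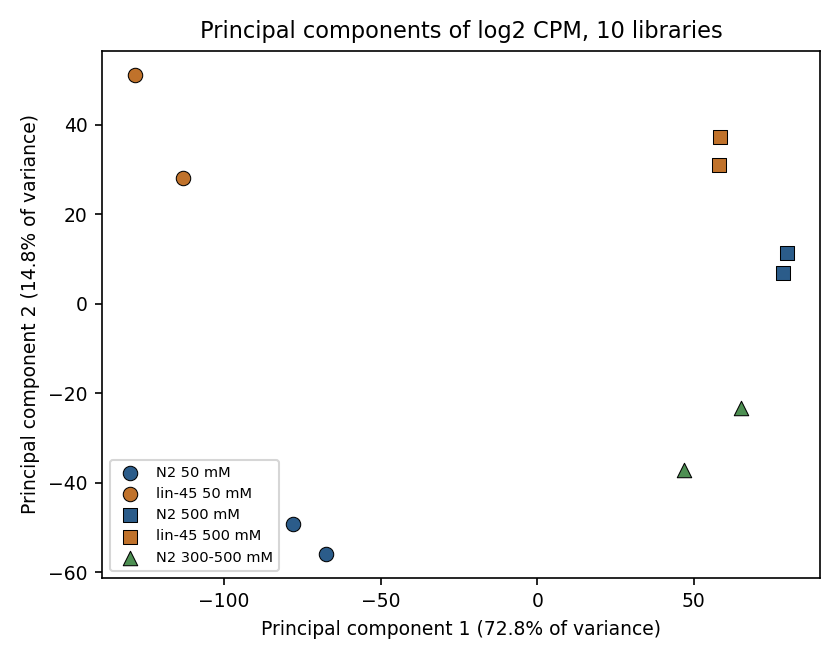
Principal component 1 (72.8% of the variance) against component 2 (14.9%) of log2 CPM, with a point for each of the 10 libraries and a colour and marker for each of the 5 groups. All libraries on 50 mM lie at or below -67.3 on component 1 and all on 500 mM at or above 46.9.

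gpdh-1 encodes glycerol 3-phosphate dehydrogenase of the glycerol pathway, whose product is the main organic osmolyte of salt-stressed worms. Its transcript stood at 3.70 ± 0.502 CPM (SD, n = 2) in N2 50 mM and 11.4 ± 2.50 in lin-45 50 mM. On 500 mM it stood at 184 ± 5.04 CPM in N2, 108 ± 1.34 in lin-45 and 82.4 ± 12.7 in preconditioned N2 (SD, n = 2 each). The paralog gpdh-2 stood at 131 ± 8.24 CPM in N2 50 mM, 292 ± 34.3 in lin-45 50 mM, 335 ± 23.98 in N2 500 mM, 347 ± 21.7 in lin-45 500 mM and 261 ± 14.9 in preconditioned embryos (SD, n = 2). The lin-45 transcript was present in the mutant, at 118 ± 1.05 CPM on 50 mM and 100.4 ± 5.27 on 500 mM, against 94.0 ± 1.42 and 85.8 ± 3.999 in N2 (SD, n = 2). It stood at 88.2 ± 9.38 CPM in preconditioned embryos. On ce10, gpdh-1 lies on chromosome I at 14075823 to 14078202 and overlaps gadr-6 on the opposite strand. gpdh-2 lies on chromosome III at 9853987 to 9859095 and lin-45 on chromosome IV at 6742526 to 6748413.

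**Figure D2:**
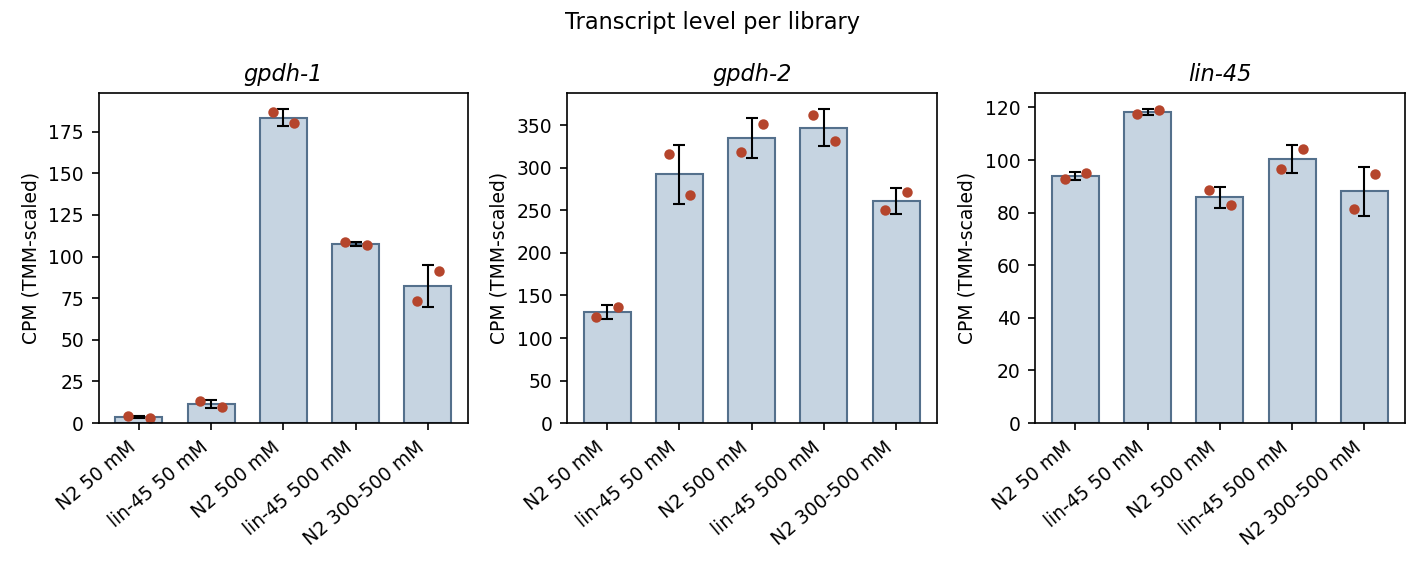
TMM-scaled CPM of gpdh-1, gpdh-2 and lin-45 in the 5 groups, with bars for group means, error bars for the SD and a point for each of 2 libraries. gpdh-1 rises from 3.70 CPM in N2 50 mM to 184 CPM in N2 500 mM, and both high-salt comparison groups stay lower, at 108 and 82.4 CPM.

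The comparison of N2 embryos on 500 and 50 mM NaCl asks how wild-type embryos respond to osmotic stress. The glycerol synthesis genes rose. gpdh-1 rose 50.0-fold (log2 5.64 ± 0.19 SE, adjusted p = 3.56e-07, 2 libraries per group, as in every comparison) and gpdh-2 rose by log2 1.35 ± 0.11 (adjusted p = 1.23e-05). The phosphatases that complete the pathway rose with them, pgph-2 by 4.64 ± 0.21 and pgph-3 by 5.09 ± 0.25. lea-1, a homologue of the late embryogenesis abundant proteins of desiccating organisms, rose by 7.59 ± 0.31, and the myo-inositol transporter genes hmit-1.1 and hmit-1.2 by 2.49 ± 0.11 and 2.76 ± 0.20. The water channel genes aqp-1 and aqp-7 fell, at -3.27 ± 0.13 and -2.12 ± 0.08. The lin-45 transcript gave -0.13 ± 0.09 (adjusted p = 0.221), which did not pass the threshold.

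The highest folds in N2 belonged to genes nearly silent on low salt. F15E6.4 stood at 106 CPM on 500 mM and had no count on 50 mM, at least 1940-fold higher. D1086.9 went from 0.0973 to 1069 CPM (log2 13.45 ± 0.63, adjusted p = 1.08e-06) and clx-1 from 0.173 to 1160 CPM (12.74 ± 0.58, adjusted p = 9.73e-07). The aldehyde dehydrogenase gene alh-2 rose by 10.60 ± 0.73 and F08H9.4 by 10.46 ± 0.54. With 1 to 3 counts on 50 mM, the lysozyme gene ilys-6 gave a count ratio of 4227 (95% interval 758.2 to 1.67e+05), C54F6.15 a ratio of 2652 (475.6 to 104800) and W02D7.11 a ratio of 1373 (246.1 to 54280). Among the deepest losses, F56A4.5 was at least 224-fold lower, E02C12.10 reached -9.41 ± 0.22 on the log2 scale, the collagen gene col-93 -7.85 ± 0.27 and the secreted protein gene scl-24 -7.76 ± 0.38. The C-type lectin genes clec-9 and clec-76 gave count ratios of 0.00236 (0.000285 to 0.00854) and 0.0031 (0.000637 to 0.00907). The glutathione transferase gene gst-37 gave 0.00418 and C45B2.3 0.00425.

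Stress and metabolic genes moved with salt in N2. Of 13 DAF-16 targets, the genes downstream of the FOXO factor of insulin signalling, 9 rose and 3 fell over all genes and over the list alone, with a median of 1.3 (camera adjusted p = 3.16e-05 with the preset and adjusted p = 0.514 with an estimated correlation). The superoxide dismutase gene sod-3 rose by 5.996 ± 0.34, the metallothionein gene mtl-1 by 5.4 ± 0.25, the ferritin gene ftn-1 by 5.29 ± 0.22 and the glyoxylate-cycle gene icl-1, C05E4.9 in the deposited table, by 2.53 ± 0.07. The insulin receptor pathway gained 7 of 10 members and lost 1 (8 and 1 adjusted over the list alone), including akt-1 (2.32 ± 0.13), daf-16 (1.67 ± 0.13) and daf-2 (1.01 ± 0.07), with adjusted p = 0.00548, and adjusted p = 0.448 with an estimated correlation. Glycolysis and gluconeogenesis rose at 15 and fell at 2 of 22 members (17 and 2 adjusted over the list alone; adjusted p = 0.00254, and adjusted p = 0.448 with an estimated correlation), with pck-2 (R11A5.4 in the table) at 1.42 ± 0.07 and hxk-1 at 0.85 ± 0.07. The small heat shock genes hsp-12.6 and hsp-12.3 rose by 8.35 ± 0.48 and 4.67 ± 0.17, while the chaperone genes hsp-4 of the endoplasmic reticulum and hsp-60 of mitochondria fell, at -2.03 ± 0.15 and -2.1 ± 0.13. Antimicrobial peptide genes went both ways, with cnc-11 up by 6.28 ± 0.34, nlp-32 up by 4.90 ± 0.33 and nlp-25 at -5.36 ± 0.40.

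Detoxification enzymes were the largest family to fall. Of 179 measured, 110 fell and 38 rose (111 and 39 adjusted over the list alone; median -1.01, adjusted p = 3.66e-10, and adjusted p = 0.458 with an estimated correlation). gst-33 gave -5.86 ± 0.15, the cytochrome P450 gene cyp-13A5 -5.81 ± 0.18 and the glucuronosyl transferase gene ugt-13 -3.41 ± 0.12. All 5 glycerol synthesis genes rose (5 adjusted over the list alone; median 4.64, adjusted p = 1.02e-08, and adjusted p = 0.448 with an estimated correlation). Of 10 genes of the adult hypertonic response 8 rose and 1 fell, also over the list alone (median 2.2, adjusted p = 5.4e-07, and adjusted p = 0.448 with an estimated correlation). Of 9 apoptosis genes 8 rose (8 adjusted over the list alone; adjusted p = 0.0253, and adjusted p = 0.448 with an estimated correlation), among them the engulfment receptor gene ced-1 at 0.83 ± 0.07 and the caspase gene ced-3 at 1.35 ± 0.21.

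Single genes of epidermal and neuronal differentiation also changed in N2 on salt. The spectrin gene sma-1 rose by 1.65 ± 0.08, the moulting regulator gene nhr-23 by 1.44 ± 0.12, the matrix genes noah-1 by 1.96 ± 0.13 and fbn-1 by 4.12 ± 0.34, and the proneural genes cnd-1 and ngn-1 by 2.44 ± 0.13 and 4.65 ± 0.38. Of 29 neuronal genes, however, 19 fell and 5 rose, also over the list alone, with a median of -0.51 that did not pass (adjusted p = 0.28). Of 18 epidermal genes 10 rose and 1 fell (adjusted p = 0.0493, and adjusted p = 0.76 with an estimated correlation). Of 26 cuticle and apical matrix genes 13 rose and 3 fell (adjusted p = 0.0275, and adjusted p = 0.886 with an estimated correlation). The epidermal and matrix counts were equal when adjusted over the list alone. Of 103 collagens 41 fell, such as col-147 at -4.82 ± 0.17, and 18 rose (39 and 18 adjusted over the list alone; adjusted p = 0.00421, and adjusted p = 0.909 with an estimated correlation). Of 78 ribosomal protein genes 50 fell and 1 rose (51 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.0312, and adjusted p = 0.922 with an estimated correlation). The epidermal, cuticle and ribosomal calls held in 3, 7 and 7 of 10 fits that each left 1 library in a group. In all, 9398 of 14802 genes passed the threshold, 4653 higher and 4745 lower on salt, and 3998 of them changed at least 2-fold.

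The same comparison in lin-45(n2018) asks how the RAF mutant responds to salt. gpdh-1 rose by 3.25 ± 0.16 (adjusted p = 1.02e-06), and pgph-2 and pgph-3 by 3.79 ± 0.20 and 4.28 ± 0.24. gpdh-2 gave 0.25 ± 0.10 and did not pass (adjusted p = 0.0607), but it passed with DESeq2 (0.0217) and with RLE (0.0274) or upper-quartile factors (0.0283). hmit-1.1 rose by 3.85 ± 0.12, hmit-1.2 by 4.62 ± 0.22 and lea-1 by 6.82 ± 0.30, while aqp-1 and aqp-7 fell, at -3.51 and -2.28. The lin-45 transcript gave -0.24 ± 0.09 (adjusted p = 0.0391), a call lost with DESeq2 (0.133), RLE (0.077) or upper-quartile factors (0.0588) and without any single library (0.0535 to 0.209).

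Nearly silent genes again had the highest folds in the mutant. clx-1 rose by 13.19 ± 0.60 (adjusted p = 6.37e-07), D1086.9 by 10.04 ± 0.50, the superoxide dismutase gene sod-5 by 9.37 ± 0.48 and F08H9.4 by 8.83 ± 0.49. C54F6.15 was at least 346-fold higher. With 1 to 3 counts on 50 mM, F15E6.4 gave a count ratio of 2254 (404.2 to 89050), W02D7.11 of 981.2 (175.8 to 38790) and alh-2 of 662 (183 to 5471). The deepest losses included E02C12.10 at -10.23 ± 0.20, gst-37 at -8.77 ± 0.37 and clec-9 at -8.59 ± 0.37. With 1 to 3 counts on 500 mM, C45B2.3, ugt-36, cyp-13A4, scl-24 and F56A4.5 gave count ratios of 0.00049, 0.000461, 0.0006, 0.0011 and 0.00232.

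Epidermal and matrix genes rose in the mutant on salt, with the cuticle collagen gene dpy-7 at 2.72 ± 0.19, noah-1 at 2.84 ± 0.14, mlt-11 at 2.98 ± 0.20 and the junction gene ajm-1 at 1.29. Of 26 cuticle and matrix genes 21 rose and 4 fell (median 2.08, adjusted p = 3.16e-05, and adjusted p = 0.645 with an estimated correlation). Of 18 epidermal genes 13 rose and 2 fell (adjusted p = 0.00272, and adjusted p = 0.6 with an estimated correlation). Collagens rose at 65 and fell at 27 of 103, also over the list alone, with a median of 1.1 that did not pass (adjusted p = 0.46). Detoxification enzymes fell at 118 and rose at 32 of 179 (median -1.29, adjusted p = 7.33e-15, and adjusted p = 0.448 with an estimated correlation), with cyp-13A5 at -7.48 ± 0.19. Ribosomal protein genes fell at 76 and rose at 1 of 78 (median -0.73, adjusted p = 3.02e-08, and adjusted p = 0.908 with an estimated correlation), with rps-12 at -1.08 ± 0.10. DAF-16 targets rose at 8 and fell at 5 of 13 (adjusted p = 0.021, and adjusted p = 0.775 with an estimated correlation), with ftn-1 at 4.37 and mtl-1 at 3.55. The insulin receptor pathway rose at 6 and fell at 1 of 10 (adjusted p = 0.0159, and adjusted p = 0.462 with an estimated correlation), with akt-1 at 2.19. The hypertonic list rose at 7 and fell at 3 of 10 (adjusted p = 0.00178, and adjusted p = 0.686 with an estimated correlation). All of these counts were equal when adjusted over the list alone. Glycerol synthesis rose at 3 of 5 members (5 adjusted over the list alone; adjusted p = 0.000256, and adjusted p = 0.448 with an estimated correlation). hsp-4 fell, at -3.95 ± 0.16, and so did gst-33, at -6.50 ± 0.15. In all, 10110 genes passed, 4949 higher and 5161 lower, and 4839 changed at least 2-fold. Of the genes called in both strains 3319 rose in both, 3605 fell in both and 327 went in opposite directions, against 1555.7 and 1654.4 expected of independent calls. Across genes, which are not independent replicates, both salt responses correlated at r = 0.866.

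The interaction asks where the mutation changes the salt response, and its values are the log2 salt effect in lin-45 minus that in N2. Of 5 glycerol synthesis genes 3 had a smaller induction in the mutant. gpdh-1 differed by -2.39 ± 0.23 (adjusted p = 0.00224), gpdh-2 by -1.105 ± 0.15 (adjusted p = 0.00541) and pgph-2 by -0.85 ± 0.27 (adjusted p = 0.047). The inositol transporter genes went the other way, with hmit-1.1 at 1.36 ± 0.16 and hmit-1.2 at 1.86 ± 0.28. The lin-45 transcript itself gave -0.11 ± 0.13 (adjusted p = 0.563). For gpdh-1 and gpdh-2 the levels on 50 mM were already higher in the mutant, by 1.62 ± 0.18 and 1.16 ± 0.11.

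Many of the strongest differences came from genes that were high in the mutant on 50 mM alone. The alpha-tubulin gene tba-8 stood at 30.96 CPM in lin-45 50 mM and at 0.829 to 0.934 CPM in the other groups, an interaction of -4.98 ± 0.47 (adjusted p = 0.0018). The collagen gene col-176 stood at 355 CPM there against 22.98 in N2 50 mM (-4.06 ± 0.35, adjusted p = 0.00143). col-149, which overlaps B0024.15 on the opposite strand, gave -6.02 ± 0.67 and the cadherin gene cdh-7 -4.86 ± 0.81. In the other direction Y68A4B.3 gave 5.35 ± 0.73, col-180 2.92 ± 0.37, C42D4.13 3.05 ± 0.52, Y53F4B.25 2.89 ± 0.52, clec-229 2.86 ± 0.51 and C30H6.5 2.86 ± 0.47. Y48G8AL.12, which overlaps Y48G8AL.1 on the opposite strand, gave 3.15 ± 0.45 and F23D12.11, which overlaps fipr-3, -3.32 ± 0.48.

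The collagen and matrix lists had a more positive salt effect in the mutant, and those of ribosomal proteins, the endoplasmic reticulum unfolded protein response and fatty acid synthesis a more negative one, calls that all ended with an estimated correlation. Ribosomal protein genes fell in both strains (medians -0.28 in N2 and -0.73 in lin-45). Of 103 collagens 52 had a more positive salt effect in lin-45 and 8 a more negative effect (59 and 9 adjusted over the list alone; median 1.07, adjusted p = 1.5e-10, and adjusted p = 0.715 with an estimated correlation), such as col-92 at 2.14 ± 0.27. Cuticle and matrix genes gave 17 and 4 of 26 (17 and 5 adjusted over the list alone; median 1.53, adjusted p = 5.84e-05, and adjusted p = 0.645 with an estimated correlation), with dpy-7 at 1.62 ± 0.26, cut-2 at 2.35 ± 0.38 and mlt-10 at 2.82 ± 0.50. Ribosomal protein genes gave 0 and 43 of 78 (0 and 75 adjusted over the list alone; median -0.44, adjusted p = 5.32e-10, and adjusted p = 0.885 with an estimated correlation). Of 18 genes of the endoplasmic reticulum unfolded protein response 11 were more negative (12 adjusted over the list alone; adjusted p = 8.09e-06, and adjusted p = 0.458 with an estimated correlation), with hsp-4 at -1.92 ± 0.20, pdi-1 at -1.01 ± 0.16 and enpl-1 at -0.76 ± 0.11. Fatty acid synthesis gave 7 of 14 more negative (7 adjusted over the list alone; adjusted p = 7.14e-05, and adjusted p = 0.448 with an estimated correlation), with elo-6 at -1.72 ± 0.15, fasn-1 at -1.26 ± 0.17 and fat-4 at -1.19 ± 0.15. Antimicrobial peptides gave 8 of 18 more negative (1 more positive and 11 more negative adjusted over the list alone; median -1.08, adjusted p = 3.49e-05, and adjusted p = 0.751 with an estimated correlation), with nlp-32 at -2.89 ± 0.42 and nlp-31 at -1.48 ± 0.19.

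Other lists called in the interaction concerned stress, metabolism, tissues and the cell cycle. DAF-16 targets gave 8 of 13 more negative (8 adjusted over the list alone; adjusted p = 0.00567, and adjusted p = 0.692 with an estimated correlation), with mtl-1 at -1.85 ± 0.30. Detoxification enzymes gave 40 more negative and 11 more positive of 179, also over the list alone (adjusted p = 0.0019, and adjusted p = 0.775 with an estimated correlation), with ugt-33 at -2.46 ± 0.20. Glycerol synthesis gave 3 of 5 more negative (4 adjusted over the list alone; adjusted p = 0.000963, and adjusted p = 0.448 with an estimated correlation). Cell cycle genes gave 5 of 31 more negative (0 adjusted over the list alone; median -0.87, adjusted p = 0.00158, and adjusted p = 0.909 with an estimated correlation). Pharynx genes gave 6 more positive and 1 more negative of 15, also over the list alone (adjusted p = 0.0432, and adjusted p = 0.844 with an estimated correlation). That call ended without N2 50 mM replicate 2 (0.0779), lin-45 50 mM replicate 2 (0.153), N2 500 mM replicate 1 (0.0871) or lin-45 500 mM replicate 1 (0.0578). Neuronal genes gave 3 and 1 of 29 (1 and 0 adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.909 with an estimated correlation), a call lost without lin-45 50 mM replicate 2 (0.269).

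The interaction passed at 3912 genes, 1801 more positive and 2111 more negative in lin-45, and 1486 of them differed at least 2-fold. The share of more positive genes was 46.0% with TMM, 57.3% with RLE, 65.8% with upper-quartile and 71.0% with total-count scaling, under which the median of all genes moved from -0.06 to 0.07. The count fell without any 1 library of the groups compared. Such fits leave 1 library in a group, so they do not single out a library. Among the 3912 genes the fitted salt effects had opposite signs at 1627, were larger in lin-45 at 1547 and smaller at 738. These signs were counted whether or not either salt effect passed, so effects near 0 are included. Over all genes, 327 passed in both strains in opposite directions.

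Comparing the strains on 50 mM asks what the mutation changes without osmotic stress. In the mutant, the lists of ribosomal proteins, fatty acid synthesis, detoxification enzymes and the endoplasmic reticulum unfolded protein response stood higher and that of cuticle and apical matrix lower, calls that all ended with an estimated correlation. gpdh-1 was higher by 1.62 ± 0.18 (adjusted p = 0.00023), gpdh-2 by 1.16 ± 0.11 (adjusted p = 0.000124) and pgph-2 by 1.25 ± 0.20, while hmit-1.1 and hmit-1.2 were lower, at -0.99 ± 0.12 and -1.27 ± 0.21. The lin-45 transcript was higher by 0.33 ± 0.09 (adjusted p = 0.0123), a call that ended without N2 50 mM replicate 1 (0.0761) or 2 (0.051) or lin-45 500 mM replicate 2 (0.0731). Among the widest differences, srw-85, a putative chemoreceptor gene, was higher by 5.25 ± 0.24, cdh-7 by 5.10 ± 0.57, tba-8 by 5.03 ± 0.29, Y41C4A.11 by 4.02 ± 0.31, col-176 by 3.95 ± 0.17, C01G10.4 by 3.75 ± 0.32 and Y47H10A.5 by 3.28 ± 0.24. col-149 was higher by 6.16 ± 0.38. F56A4.3 and irld-35 had no count in the mutant on 50 mM, at least 528.5-fold and 391.8-fold lower. Y68A4B.3 was lower, at -3.96 ± 0.39, R05D8.11 at -3.53 ± 0.36, W03D8.11 at -3.47 ± 0.58, Y64H9A.2 at -3.41 ± 0.37 and F32B4.8 at -3.38 ± 0.26.

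Fold changes on 50 mM had a median over all genes of 0.16, against which list medians are read. All 78 ribosomal protein genes were higher (78 adjusted over the list alone; median 0.55, adjusted p = 2.13e-10, and adjusted p = 0.865 with an estimated correlation), with rps-15 at 1.55 ± 0.09. Of 179 detoxification enzymes 113 were higher and 14 lower (116 and 15 adjusted over the list alone; median 0.78, adjusted p = 1.1e-09, and adjusted p = 0.462 with an estimated correlation), with cyp-13A5 at 2.39 ± 0.14. Fatty acid synthesis was higher at 11 of 14 (12 adjusted over the list alone; median 1.12, adjusted p = 2.88e-06, and adjusted p = 0.448 with an estimated correlation), with elo-5 at 2.44 ± 0.19 and elo-6 at 1.49 ± 0.11. Antimicrobial peptides were higher at 14 of 18 (14 adjusted over the list alone; adjusted p = 6.17e-06, and adjusted p = 0.692 with an estimated correlation), with cnc-2 at 3.27 ± 0.28 and nlp-27 at 2.14 ± 0.13. The unfolded protein response of the endoplasmic reticulum was higher at 15 and lower at 1 of 18, also over the list alone (adjusted p = 0.00265, and adjusted p = 0.645 with an estimated correlation), with hsp-4 at 2.05 ± 0.15. Heat shock proteins were higher at 8 of 19 (7 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.645 with an estimated correlation), with hsp-1 at 1.01 ± 0.08. Glycolysis was higher at 16 of 22 (17 adjusted over the list alone; adjusted p = 0.00281, and adjusted p = 0.448 with an estimated correlation), with enol-1 at 0.95 ± 0.08. Cell cycle genes were higher at 18 of 31 (18 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.914 with an estimated correlation).

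Matrix and epidermal genes were lower in the mutant on 50 mM. Of 26 cuticle and matrix genes 18 were lower and 4 higher, also over the list alone (median -1.82, adjusted p = 1.11e-06, and adjusted p = 0.6 with an estimated correlation), with dpy-7 at -2.25 ± 0.19, the lipocalin gene lpr-3 at -2.35 ± 0.25 and rol-8 at 5.32 ± 0.50. Of 18 epidermal genes 10 were lower and 1 higher, also over the list alone (adjusted p = 0.00102, and adjusted p = 0.551 with an estimated correlation), with bus-8 at -2.35 ± 0.27 and ajm-1 at -0.94 ± 0.10. Of 103 collagens 53 were lower and 25 higher (56 and 27 adjusted over the list alone; adjusted p = 0.00289, and adjusted p = 0.909 with an estimated correlation), with col-98 higher by 2.62 ± 0.18. The proneural gene cnd-1 was lower, at -1.51 ± 0.16. Glycerol synthesis (3 of 5 higher, also over the list alone; adjusted p = 0.0391, and adjusted p = 0.645 with an estimated correlation) lost its call without N2 50 mM replicate 1 (0.0524). DAF-16 targets (10 of 13 higher, also over the list alone; adjusted p = 0.017, and adjusted p = 0.76 with an estimated correlation) lost theirs without lin-45 50 mM replicate 2 (0.0563). So did insulin-like peptides (13 higher and 2 lower of 23, 15 and 2 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.668 with an estimated correlation), also at 0.0563. In all, 8038 genes passed, 4921 higher and 3117 lower, and 2559 differed at least 2-fold. The count fell without any 1 library of either group, which leaves 1 there. The share of higher genes was 61.2% with TMM, 56.4% with RLE, 51.3% with upper-quartile and 46.9% with total-count scaling, under which the median of all genes was 0.03. Of 27 maternal germline transcripts 2 were higher and 3 lower (2 and 2 adjusted over the list alone), with a median of 0.11, a mean of 0.17 and a camera direction of down that did not pass (adjusted p = 0.806).

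Comparing the strains on 500 mM asks what the mutation changes under osmotic stress. gpdh-1 was lower in the mutant by log2 -0.77 ± 0.15 (adjusted p = 0.0179). That call ended without any 1 library of either group, which leaves that group with 1 library. gpdh-2 gave 0.05 ± 0.10 (adjusted p = 0.81) and lin-45 0.23 ± 0.09 (adjusted p = 0.17), neither past the threshold. The cathepsin B-like protease gene cpr-3 was higher by 4.59 ± 0.20 (adjusted p = 1.88e-05), srw-85 by 4.83 ± 0.23, K08D8.4 by 3.52 ± 0.17, B0024.4 by 3.45 ± 0.14, Y47H10A.5 by 3.39 ± 0.25, R09F10.1 by 2.59 ± 0.22, F44G3.10 by 2.45 ± 0.14 and the astacin protease gene nas-9 by 2.42 ± 0.21. The nuclear receptor gene nhr-12 was lower, at -3.20 ± 0.10 (adjusted p = 3.08e-06), as were clec-209 at -3.31 ± 0.25, F29B9.1 at -1.95 ± 0.14 and the monocarboxylate transporter gene mct-1 at -1.50 ± 0.11. irld-35 had no count in the mutant, at least 299-fold lower, and F56A4.3 had a count ratio of 0.00188 (0.000227 to 0.00681).

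Single genes of fatty acid elongation, the small heat shock family and collagens stood higher in the mutant on 500 mM, with elo-5 at 1.75 ± 0.21, elo-1 at 1.06 ± 0.14, hsp-17 at 1.87 ± 0.14 and col-103 at 2.33 ± 0.18. Heat shock proteins were higher at 4 of 19 (5 adjusted over the list alone; adjusted p = 1.12e-05, and adjusted p = 0.448 with an estimated correlation). Detoxification enzymes were higher at 30 and lower at 3 of 179 (39 and 5 adjusted over the list alone; adjusted p = 8.09e-06, and adjusted p = 0.645 with an estimated correlation), with cyp-33C8 at 1.66 ± 0.09 and ugt-33 at -1.71 ± 0.16. Collagens were higher at 21 and lower at 3 of 103 (28 and 6 adjusted over the list alone; adjusted p = 3.49e-05, and adjusted p = 0.908 with an estimated correlation). Glycolysis was higher at 6 of 22 (13 higher and 1 lower adjusted over the list alone; adjusted p = 0.00102, and adjusted p = 0.448 with an estimated correlation), with enol-1 at 0.63 ± 0.08. Fatty acid synthesis was higher at 3 of 14 (5 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.582 with an estimated correlation). Cuticle and matrix genes were lower at 1 of 26 (1 adjusted over the list alone; median -0.44, adjusted p = 0.00134, and adjusted p = 0.749 with an estimated correlation) and epidermal genes at 1 of 18 (0 adjusted over the list alone; adjusted p = 0.00349, and adjusted p = 0.634 with an estimated correlation).

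Ribosomal protein genes were higher at 2 of 78 in the mutant on 500 mM (2 adjusted over the list alone; adjusted p = 0.0296, and adjusted p = 0.922 with an estimated correlation), with rps-15 at 1.06 ± 0.09. The list call ended without N2 500 mM replicate 2 (0.166), lin-45 500 mM replicate 1 (0.251) or N2 300-500 mM replicate 1 (0.0688) or 2 (0.0667). In all, 961 genes passed, 717 higher and 244 lower, and 358 differed at least 2-fold. The count fell without any 1 library of either group, which leaves that group with 1. It rose without either preconditioned library, whose spread enters the pooled estimate. With only the groups compared it was 2897. Of the 961 genes 773 (80.4%) also differed on 50 mM, 567 higher and 167 lower at both levels and 39 in opposite directions, against 238.4 and 51.4 expected of independent calls. Across genes, both strain effects correlated at r = 0.484. A total of 276 genes separated the strains at both salt levels with no overlap between libraries, 185 higher and 91 lower in the mutant.

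Comparing preconditioned with other N2 embryos on 500 mM asks what exposure of the parents to 300 mM changes in stressed offspring. Several genes that salt raises stood lower after preconditioning. gpdh-1 was lower at -1.16 ± 0.15 (adjusted p = 0.00133), pgph-3 at -0.99 ± 0.21, lea-1 at -2.48 ± 0.24 and dur-1 at -2.03 ± 0.23. gpdh-2 gave -0.36 ± 0.10 (adjusted p = 0.0396), a call lost in several fits that leave 1 library in a group. The lin-45 transcript gave 0.04 ± 0.09 (adjusted p = 0.782). The small heat shock genes hsp-12.6 and hsp-12.3 were lower at -3.48 ± 0.34 and -2.33 ± 0.15, ilys-6 at -5.40 ± 0.42 (adjusted p = 0.000308), nlp-32 at -3.65 ± 0.30 and the acyl-CoA synthetase gene acs-2 at -3.51 ± 0.50. acdh-2, which overlaps ins-13 on the same strand, gave -4.56 ± 0.40, C54F6.6 -3.83 ± 0.37, C54F6.15 -3.78 ± 0.45 and F21F3.3 -3.53 ± 0.38. Among genes that stood higher were R05D8.11 at 2.78 ± 0.34 (adjusted p = 0.00112), Y69H2.14 at 1.68 ± 0.19, col-103 at 1.59 ± 0.18, F58G6.9 at 1.56 ± 0.10, ZK6.11 at 1.56 ± 0.17, T07D3.4 at 1.52 ± 0.10, col-147 at 1.502 ± 0.15 and C15C8.3, which overlaps C15C8.7, at 1.67 ± 0.16.

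Some stress, defence and metabolism lists were lower after preconditioning. DAF-16 targets were lower at 10 and higher at 1 of 13, also over the list alone (median -1.35, adjusted p = 5.47e-10, and adjusted p = 0.448 with an estimated correlation), with mtl-1 at -1.92 ± 0.21, ftn-1 at -1.90 ± 0.18 and icl-1 (C05E4.9) at -1.27 ± 0.07. The hypertonic list was lower at 7 of 10 (7 adjusted over the list alone; median -1.1, adjusted p = 2.86e-09, and adjusted p = 0.448 with an estimated correlation). Antimicrobial peptides were lower at 10 and higher at 1 of 18 (11 and 1 adjusted over the list alone; adjusted p = 2.8e-08, and adjusted p = 0.645 with an estimated correlation), with cnc-4 at -1.59 ± 0.13. Glycolysis was lower at 13 of 22 (13 adjusted over the list alone; adjusted p = 8.91e-07, and adjusted p = 0.448 with an estimated correlation), with the hexokinase gene hxk-1 at -1.01 ± 0.07 and pck-2 (R11A5.4) at -0.75 ± 0.07. Trehalose metabolism was lower at 6 of 8 (7 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.645 with an estimated correlation), with tps-1 at -0.82 ± 0.12. Fatty acid synthesis was lower at 7 of 14 (9 adjusted over the list alone; adjusted p = 0.000425, and adjusted p = 0.448 with an estimated correlation), with fat-6 at -1.70 ± 0.19. The insulin receptor pathway was lower at 5 and higher at 1 of 10 (6 and 2 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.463 with an estimated correlation), with akt-1 at -1.03 ± 0.12 and daf-2 at -0.62 ± 0.07.

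Other list calls of preconditioning ended when single libraries were left out, most with medians close to those of all libraries. Glycerol synthesis, lower at 3 of 5 (3 adjusted over the list alone; adjusted p = 0.0336, and adjusted p = 0.645 with an estimated correlation), lost its call without N2 300-500 mM replicate 1 (0.174; median -0.38 against -0.36 in all libraries). Without that library, epidermal genes (7 of 18 higher, 9 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.645 with an estimated correlation) gave 0.0716 (0.22 against 0.24). Ribosomal protein genes (3 of 78 lower, 2 adjusted over the list alone; adjusted p = 0.00333, and adjusted p = 0.914 with an estimated correlation) then gave 0.231 (-0.12 against -0.15). Germline precursor genes (5 of 15 higher, 5 adjusted over the list alone; adjusted p = 0.0255, and adjusted p = 0.886 with an estimated correlation) gave 0.588 without it (0.04 against 0.37) and 0.0572 without N2 500 mM replicate 1 (0.28). Core histones (7 lower and 2 higher of 28, also over the list alone; adjusted p = 0.00957, and adjusted p = 0.909 with an estimated correlation) gave 0.268 without N2 300-500 mM replicate 2 (-0.79 against -1.02). Heat shock proteins were lower at 5 of 19 (6 lower and 1 higher adjusted over the list alone), with a median of 0.18, a mean of -0.14 and a camera direction of down (adjusted p = 0.0432, and adjusted p = 0.76 with an estimated correlation). That call ended without N2 500 mM replicate 1 (0.105), lin-45 500 mM replicate 1 (0.051) or 2 (0.0615) or N2 300-500 mM replicate 2 (0.734). The epidermal regulators lin-26 and elt-3 were higher by 0.60 ± 0.07 and 0.57 ± 0.08, and the germline helicase gene glh-1 by 0.48 ± 0.08.

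In all, 3292 genes passed, 1514 higher and 1778 lower after preconditioning, and 821 differed at least 2-fold, 198 higher and 623 lower. The count was 1359 (483 higher and 876 lower) with only the groups compared. It also fell without either N2 500 mM library, which leaves 1 in that group. The share of higher genes was 46.0% with TMM and 61.5% with total-count scaling, under which the median of all genes moved from 0.05 to 0.13.

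Stage markers differed inside the preconditioned pair. Replicate 2 minus replicate 1 gave a median log2 difference of -3.32 over 9 transient early zygotic genes, -1.304 over 31 cell cycle genes and -1.01 over 27 maternal germline transcripts. Early zygotic genes took 0.00983% of the counts in replicate 1 and 0.00240% in replicate 2. Against the mean of N2 500 mM, replicate 1 stood at 1.89 for early zygotic and 0.72 for cell cycle genes and replicate 2 at -1.16 and -0.52. DAF-16 targets (-1.53, -1.24) and the hypertonic list (-1.27, -0.93) lay lower in both, unlike heat shock genes (0.16, -0.62). Ribosomal RNA, which polyadenylated selection depletes, took 0.0061% and 0.0064% of counts here against 0.029% and 0.0259% in N2 500 mM. With it, the mitochondrial ribosomal RNA gene MTCE.33, which overlaps nduo-3, was lower by -7.95 ± 1.56 (adjusted p = 0.00859) and core histones had a median of -1.02. These histones also differed inside the N2 50 mM and lin-45 50 mM pairs, by -1.101 and -1.21, where the ribosomal RNA share fell from 0.205% to 0.0217% and from 0.168% to 0.0446%.

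**Figure D3:**
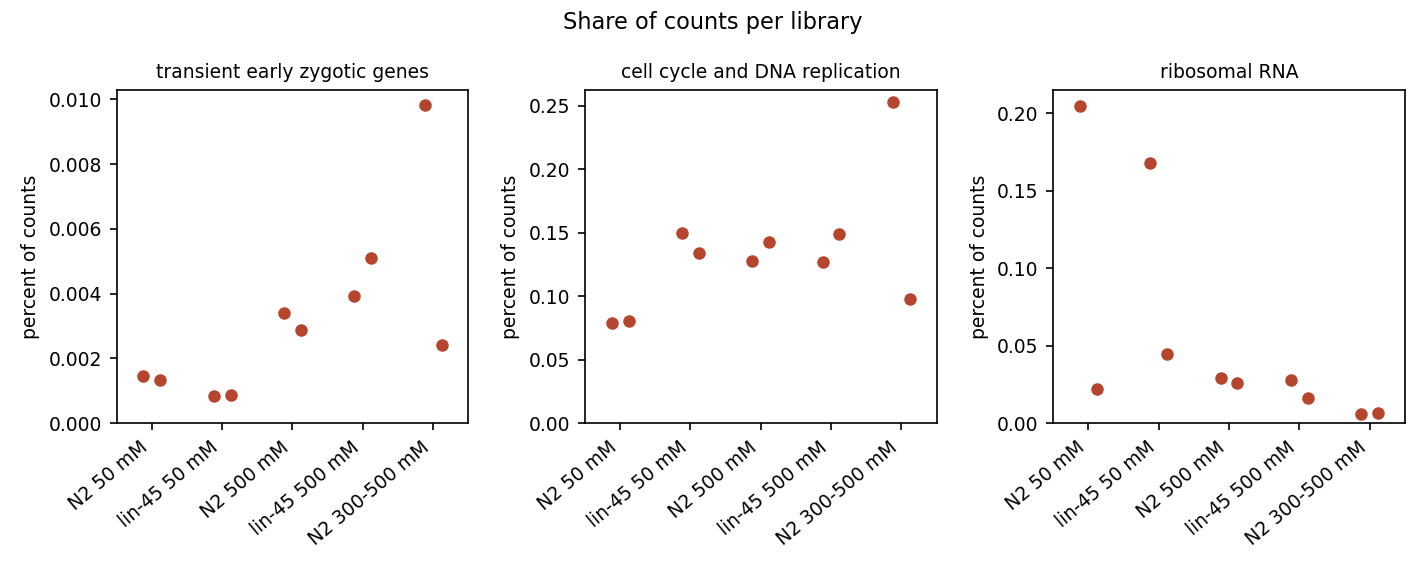
Percent of counts per library taken by transient early zygotic genes, by cell cycle and DNA replication genes and by ribosomal RNA, with a point for each of 2 libraries in the 5 groups. The preconditioned libraries differ most for early zygotic (0.00983% and 0.00240%) and cell cycle genes (0.253% and 0.0980%) and hold the least ribosomal RNA (0.0061% and 0.0064%).

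Comparing preconditioned embryos on 500 mM with N2 on 50 mM asks what remains of the salt response after parental exposure. gpdh-1 was higher by 4.49 ± 0.18 (adjusted p = 8.06e-07), gpdh-2 by 0.99 ± 0.11 (adjusted p = 0.000104), pgph-2 by 4.49 and lea-1 by 5.11 ± 0.28, while lin-45 gave -0.09 ± 0.09 (adjusted p = 0.391). F15E6.4 was at least 240-fold higher, D1086.9 higher by 11.12 ± 0.63, clx-1 by 10.32 ± 0.57, alh-2 by 7.40 ± 0.79, R09E10.13 by 7.15 ± 0.46, F08H9.4 by 7.13 ± 0.52, the acyl-CoA dehydrogenase gene acdh-1 by 6.79 ± 0.35 and C37A5.5 by 6.79 ± 0.43. F56A4.5 was at least 298.6-fold lower, and E02C12.10 was lower at -8.52 ± 0.19, cyp-33D3 at -7.84 ± 0.45 and C45B2.3 at -7.20 ± 0.45. clec-13 and clec-15, whose counts were identical, gave -9.37 ± 0.36, and clec-76 gave a count ratio of 0.00155 (0.000188 to 0.00562). MTCE.33 gave -8.60 ± 1.57 beside its lower ribosomal RNA share.

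All 5 glycerol synthesis genes were higher than on 50 mM (5 adjusted over the list alone; median 4.10, adjusted p = 7.29e-09, and adjusted p = 0.448 with an estimated correlation), and detoxification enzymes were lower at 116 and higher at 27 of 179 (116 and 28 adjusted over the list alone; adjusted p = 1.08e-18, and adjusted p = 0.448 with an estimated correlation). Apoptosis genes were higher at 9 of 9 (9 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.448 with an estimated correlation), with ced-3 at 1.44. Epidermal genes were higher at 13 of 18 (adjusted p = 0.000106, and adjusted p = 0.458 with an estimated correlation), with nhr-23 at 1.64. Cuticle and matrix genes were higher at 13 and lower at 2 of 26 (adjusted p = 0.00265, and adjusted p = 0.76 with an estimated correlation), and the hypertonic list at 6 and 3 of 10 (adjusted p = 0.0036, and adjusted p = 0.692 with an estimated correlation). Maternal germline transcripts were higher at 24 and lower at 2 of 27 (adjusted p = 0.0075, and adjusted p = 0.909 with an estimated correlation), with pie-1 at 1.44 ± 0.29, and germline precursor genes higher at 12 of 15 (adjusted p = 0.0112, and adjusted p = 0.86 with an estimated correlation). Collagens were lower at 34 and higher at 15 of 103 (adjusted p = 0.0036, and adjusted p = 0.909 with an estimated correlation). These 6 counts were equal when adjusted over the list alone. Ribosomal protein genes were lower at 74 and higher at 2 of 78 (75 and 2 adjusted over the list alone; adjusted p = 1.74e-05, and adjusted p = 0.909 with an estimated correlation). Cell cycle genes were higher at 20 of 31 (21 adjusted over the list alone; adjusted p = 0.00594, and adjusted p = 0.914 with an estimated correlation), a call lost without N2 300-500 mM replicate 1 (0.17). DAF-16 targets were higher at 7 and lower at 5 of 13, also over the list alone (adjusted p = 0.0323, and adjusted p = 0.838 with an estimated correlation), a call lost without N2 50 mM replicate 1 (0.174). In all, 8624 genes passed, 4493 higher and 4131 lower, and 3144 differed at least 2-fold.

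Several lists passed in no comparison. On salt in N2, aquaporins and inositol transporters rose at 5 and fell at 7 of 14, the mitochondrial unfolded protein response at 1 and 3 of 7, body wall muscle at 4 and 12 of 28, and intestine at 6 and 10 of 17. All of these counts were equal when adjusted over the list alone. Hypoxia genes rose at 1 and fell at 1 of 9 (0 and 0 adjusted over the list alone) and mitochondrially encoded genes at 0 and 1 of 11 (0 and 0 adjusted over the list alone). Vitellogenins rose at 1 and fell at 1 of 3 (1 and 1 adjusted over the list alone), with a median of 0.37, a mean of -0.41 and a camera direction of down. Of the 2 measured sperm genes, too few for a test, 1 rose. The RAS and ERK pathway to which lin-45 belongs rose at 5 and fell at 6 of 18, with a median of -0.08, a mean of 0.02 and a camera direction of up. It had 0 members past the threshold in the interaction and between the strains on 500 mM, and 2 higher and 3 lower on 50 mM.

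**Figure D4:**
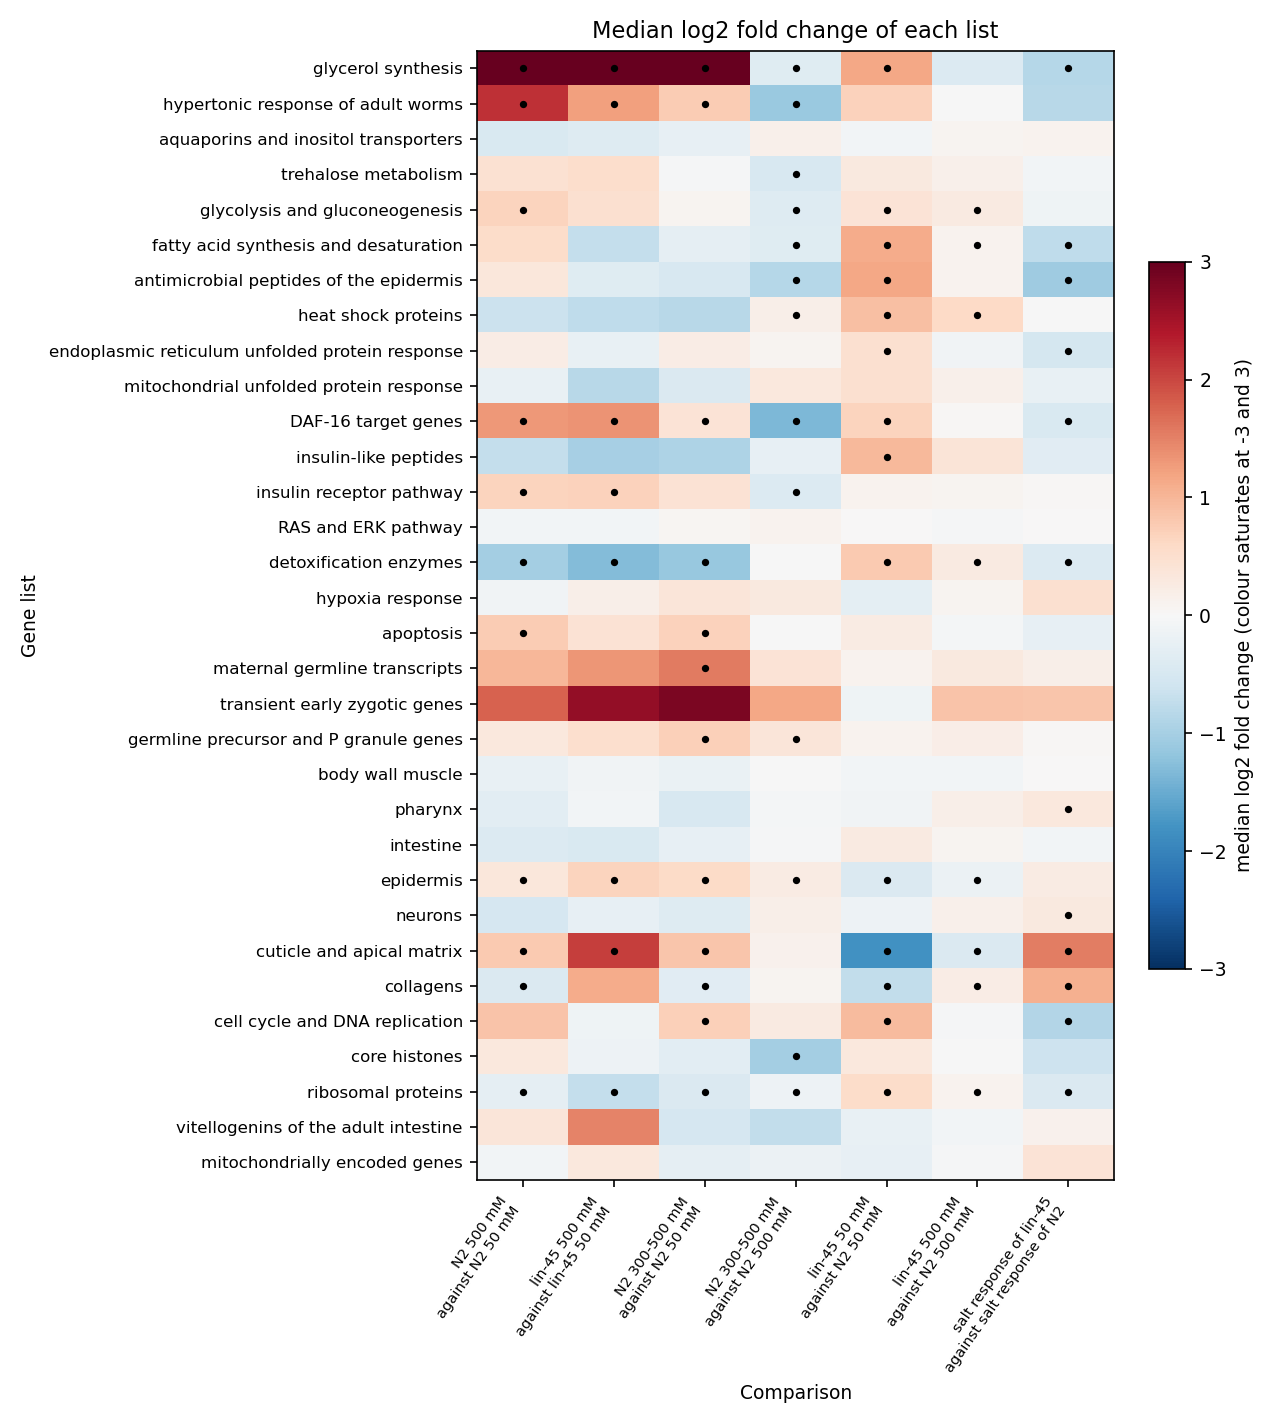
Median log2 fold change of each tested gene list (vertical axis) in each of the 7 comparisons (horizontal axis), with colour from -3 to 3 and a dot where the camera test passed with the preset correlation. Glycerol synthesis reaches medians of 4.64, 3.25 and 4.10 in the salt comparisons, and no dot remains with an estimated correlation.

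Lists of embryo stage markers did not pass on salt in N2 or in lin-45. A stage difference between salt levels stays open, since the called members of these lists mostly rose in N2. Of 27 maternal germline transcripts 14 rose and 2 fell in N2 (median 0.99, adjusted p = 0.173) and 18 rose and 2 fell in lin-45 (median 1.32, adjusted p = 0.0843), also over the lists alone. Of 31 cell cycle genes 14 rose and 0 fell in N2, also over the list alone (median 0.86, adjusted p = 0.0634), while 5 rose and 7 fell in lin-45 (3 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.945). Of 9 early zygotic genes 1 rose in N2, also over the list alone (median 1.77, adjusted p = 0.316). In lin-45 on salt 7 rose (8 adjusted over the list alone; median 2.63, adjusted p = 0.107), and 7 were higher in preconditioned embryos against N2 50 mM (8 adjusted over the list alone; median 2.82, adjusted p = 0.107).

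Setting the effects beside each other asks whether preconditioning moves genes as the mutation or salt does. Preconditioning and the strain effect on 50 mM, which share no library, correlated at r = -0.156 across genes (jackknife SE 0.0732). Simulations gave a median of 0.005 (-0.063 to 0.054), and the covariance was -0.0893 against 0.000379. Of the genes called in both, 486 were higher in both (503.3 expected of independent calls), 129 lower in both (374.4), 544 higher then lower (318.8) and 824 lower then higher (591.1). Preconditioning and the strain effect on 500 mM, which share the N2 500 mM libraries, correlated at 0.242 (jackknife SE 0.229). Shared libraries alone gave 0.508 in simulations (0.458 to 0.571). These correlations are not comparable, because real effects add variance in the data only. The covariance was 0.0776 against 0.0334 in simulations. The first correlation was -0.243 over genes of at least 10 CPM, -0.310 over the most abundant genes, a set chosen after seeing the data, and -0.0969 without N2 300-500 mM replicate 2. The second was 0.0723 and -0.0202 over these genes, 0.423 without N2 500 mM replicate 1 and 0.146 without lin-45 500 mM replicate 2. For the strain effect on 500 mM, 171 genes were higher in both (73.3 expected) and 36 lower in both (29.3).

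Preconditioning tended to run against the salt response. It correlated at -0.296 (jackknife SE 0.153) with the salt response of lin-45, with which it shares no library (covariance -0.295). Simulations gave a median of -0.0019 there (-0.0715 to 0.0605), a range that leaves out variation shared between genes. Preconditioning correlated at -0.495 (jackknife SE 0.193) with the salt response of N2, with a covariance of -0.462 against -0.033 in simulations. Shared libraries alone gave a correlation of -0.502 in simulations, but these hold no real effects, so the correlations are not comparable. Of the genes called for preconditioning and for salt in lin-45, 873 were higher then lower (527.9 expected) and 1133 lower then higher (594.5), with 275 higher in both (506.2) and 296 lower in both (619.9). The 2560 genes that salt raised at least 2-fold in lin-45 had a median preconditioning effect of -0.10, with 654 lower and 58 higher. The 2279 genes that salt lowered had a median of 0.23, with 439 higher and 129 lower. Against N2 50 mM, preconditioned embryos kept a median change of 0.86 for the raised and -1.27 for the lowered genes, where other N2 embryos on 500 mM had 1.22 and -1.42. Without N2 300-500 mM replicate 2 the correlation with the salt response of lin-45 was -0.190, and without replicate 1 it was -0.400.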

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

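Of the tests weighed here, that of embryo age and the total-count scaling were chosen only after the result was seen. The edgeR interaction test, which asks whether the salt response differs between lin-45 and N2, passed at 3912 genes, and its named genes and called lists are given here because a difference between groups was tested and found. The salt effect in lin-45 minus that in N2 was -2.39 for gpdh-1 and -1.105 for gpdh-2, both smaller inductions in the mutant. It was 5.35 for Y68A4B.3, 3.15 for Y48G8AL.12, 3.05 for C42D4.13, 2.92 for col-180, 2.89 for Y53F4B.25, 2.86 for clec-229, 2.86 for C30H6.5 and 2.83 for grd-2. It was -6.02 for col-149, -4.98 for tba-8, -4.86 for cdh-7, -4.06 for col-176, -3.32 for F23D12.11, -3.29 for Y41C4A.11, -3.05 for Y37D8A.3 and -2.99 for spp-17. Calls of 4 of these genes ended when single libraries were left out. grd-2 gave adjusted p values from 0.0551 (without lin-45 500 mM replicate 1) to 0.114 (without lin-45 500 mM replicate 2) in 6 such fits, and spp-17 from 0.0683 (without lin-45 50 mM replicate 1) to 0.268 (without N2 500 mM replicate 2) in 5. Y41C4A.11 gave 0.058 without N2 500 mM replicate 2, and Y37D8A.3 gave 0.0567 without N2 50 mM replicate 1 and 0.0648 without N2 500 mM replicate 2.

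Called lists whose median salt response was more negative in lin-45 were glycerol synthesis (-0.85), fatty acid synthesis and desaturation (-0.76), antimicrobial peptides of the epidermis (-1.08), the endoplasmic reticulum unfolded protein response (-0.54), DAF-16 targets (-0.47), detoxification enzymes (-0.40), cell cycle and DNA replication (-0.87) and ribosomal proteins (-0.445). Lists with a more positive median were pharynx (0.31), neurons (0.28), cuticle and apical matrix (1.53) and collagens (1.07). With an estimated correlation none of these calls held (adjusted p 0.448 to 0.909). The pharynx call ended without N2 50 mM replicate 2 (0.0779), lin-45 50 mM replicate 2 (0.153), N2 500 mM replicate 1 (0.0871) or lin-45 500 mM replicate 1 (0.0578), and the neuron call without lin-45 50 mM replicate 2 (0.269).

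The pattern behind these differences is that many more genes separate the strains on 50 mM (8038) than on 500 mM (961), a ratio of 8.36. Scaling is argued against, since under RLE, upper-quartile and total-count scaling the ratio stayed at or above 6.35. A single deviant library stays open. The ratio was 3.88 without N2 300-500 mM replicate 2, below the bound of 4 set before the result was seen, and 4.69 was the lowest value without a library of the 4 groups compared (lin-45 50 mM replicate 1). It rose to 17.2 to 32.2 without a library of the strains on 500 mM, the highest without N2 500 mM replicate 2. The size of the ratio depends on the pooled spread, because with only the groups compared 2897 genes passed on 500 mM and the ratio was 2.77.

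A difference in embryo age at collection between the strains also stays open. If lin-45 embryos on 50 mM were younger, maternal germline transcripts could stand higher in them. Their median difference was 0.11, with a bootstrap interval of -0.041 to 0.328 over 27 genes, which includes 0. The median of all genes was 0.16. The bootstrap resamples genes as if independent, so its interval does not measure the spread between libraries. Cell cycle genes, by contrast, were higher in lin-45 on 50 mM at 18 of 31 with 0 lower (median 0.96, adjusted p = 0.0156, and adjusted p = 0.914 with an estimated correlation), which goes with younger embryos. Early zygotic genes go against them, with 0 higher and 1 lower of 9 (median -0.12, adjusted p = 0.418) and 0.000851% and 0.000873% of the counts against 0.00146% and 0.00132% in N2. Lower cuticle and matrix genes (18 lower and 4 higher of 26) and epidermal genes (10 lower and 1 higher of 18) in lin-45 on 50 mM could also go with younger embryos. Intestinal genes, however, took more of its counts (0.7934% and 0.7791% against 0.5625% and 0.6189% in N2). Muscle genes took a similar share (3.121% and 3.063% against 3.124% and 3.196%). Age and genotype cannot be told apart here, because these lists go both ways and no library records the stage of its embryos. An effect of the RAF mutation itself, on the rate of development or on gene activity, remains among the open explanations and was not tested apart from these. The stage lists did not pass between salt levels in N2 or lin-45 embryos of parents on 50 mM, so a stage difference stays open there too. In preconditioned embryos against N2 50 mM, the maternal germline and cell cycle lists did pass, calls that ended with an estimated correlation.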

How the results depend on the processing

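Total-count scaling and the correlations over the most abundant genes were chosen after seeing the data. Where no cause is given, the cause was not tested. Alternatives planned for normalized values, which concern a pseudocount and a filter on such values, were not run because counts were deposited.

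The counts of called genes stayed within 1.5 times their main values in all 7 comparisons with DESeq2, limma-voom, RLE, upper-quartile or total-count scaling, no filter and a minimum of 5 CPM. Of the genes called by edgeR, DESeq2 also called 92.0%, 92.3%, 79.7%, 85.8%, 93.3%, 88.2% and 91.0% in N2 on salt, lin-45 on salt, the interaction, the strains on 50 and 500 mM, preconditioning, and preconditioned against N2 50 mM, with 0 in the opposite direction. Requiring a fold of at least 2 left, in the same order, 3998, 4839, 1486, 2559, 358, 821 and 3144 genes, fewer by construction. With only the groups compared, 2897 genes passed between the strains on 500 mM (1638 higher and 1259 lower) in place of 961, and 1359 passed for preconditioning (483 higher and 876 lower) in place of 3292. The root mean square log2 difference within pairs was 0.323 in N2 500 mM and 0.269 in lin-45 500 mM, against 0.587 in the preconditioned pair. By construction, the fit of all groups pools these spreads, which widens the first comparison and narrows the second.

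Left-out libraries moved some counts further, partly because a group left with 1 library lacks replication and is assumed to vary like the others. The interaction ranged from 787 without N2 50 mM replicate 1 to 5291 without N2 300-500 mM replicate 1, the strains on 50 mM from 5188 without N2 50 mM replicate 1 to 8568 without N2 300-500 mM replicate 1, the strains on 500 mM from 240 without N2 500 mM replicate 2 to 2206 without either preconditioned library, and preconditioning from 1430 without N2 500 mM replicate 2 to 4260 without N2 300-500 mM replicate 1. N2 on salt (7240 to 10302), lin-45 on salt (8533 to 10972), preconditioned against N2 50 mM (5850 to 9325) and the called list tests (75 to 84) moved by less than 1.5 times.

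All 78 list calls were lost with an estimated correlation. They all remained under RLE, and 61 remained whichever library was left out. Of 808 named gene values, 17 lost their call with DESeq2, 9 with RLE, 15 with upper-quartile factors and 168 without some single library, while 1, 1, 1 and 2 gained a call. No called list changed the sign of its median under any scaling.

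Across genes, the correlation of preconditioning with the strain effect on 50 mM went from -0.156 to -0.243 for genes with a mean of at least 10 CPM and to -0.310 for the most abundant genes. The correlation with the strain effect on 500 mM went from 0.242 to 0.0723 for genes of at least 10 CPM and reversed to -0.0202 in the most abundant genes. Over left-out libraries the correlations ranged from -0.195 to -0.0969 with the strain effect on 50 mM, 0.146 to 0.423 with that on 500 mM, -0.602 to -0.335 with the salt response of N2 and -0.400 to -0.190 with that of lin-45.

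The labels do not say whether replicate numbers pair the libraries. Correlations of replicate differences between groups ranged from -0.229 to 0.146 over 10 pairs of groups, which does not exclude shared handling. Core histones, for example, fell from replicate 1 to 2 in both N2 50 mM (-1.101) and lin-45 50 mM (-1.21). With the replicate number as a block, counts were 8972, 9792, 2928, 7592, 660, 2649 and 8152 for N2 on salt, lin-45 on salt, the interaction, the strains on 50 and 500 mM, preconditioning, and preconditioned against N2 50 mM. Under it 28 of the 808 named gene values and 1 of the 78 list calls were lost. Genes at low counts are limited by depth, and folds with up to 3 counts in a group were given as bounds or count ratios.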

Other observations

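Gene classes taken from name prefixes add families outside the lists. The prefixes and their 749 tests over 107 classes of at least 10 tested members were chosen after seeing the data, and no class passed with an estimated correlation (lowest adjusted p = 0.961). The F-box family fbxb was raised by salt at 63 of 80 members and lowered at 2 in N2 (median 3.38), raised at 73 and lowered at 1 in lin-45 (4.12), and higher at 71 and lower at 1 in preconditioned embryos against N2 50 mM (3.42). Lectin genes of the clec family fell at 78 and rose at 10 of 108 in N2 on salt (median -1.59). FMRFamide-like peptide genes (flp) fell at 26 of 30 with 0 rising, and the twk potassium channel genes fell at 29 and rose at 1 of 40. Autophagy genes (atg) rose at 11 of 13 (median 0.64).

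Between the strains on 50 mM, nucleoporin genes (npp) were higher in the mutant at 19 of 21 (median 0.73), proteasome regulatory subunits (rpn) at 11 of 12 (0.86) and translation initiation factors (eif) at 13 of 13. The cuticulin-like family cutl was lower at 22 of 27 (median -1.12), the hedgehog-related family grl at 15 of 21 with 1 higher (-1.97) and the patched-related family ptr at 18 of 23 with 4 higher (-1.15). The ciliary dyf genes were lower at 11 of 11 (-0.82). After preconditioning, the transthyretin-like family ttr was lower at 22 and higher at 1 of 49 (median -0.57) and the dehydrogenase family dhs lower at 15 of 30 (-0.59). On 500 mM, the F-box family fbxa was higher in the mutant at 21 and lower at 2 of 115 (0.34).

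Among the tests that follow, those of shared libraries, of depth in the most abundant genes, of embryo age, of linkage and of chance neighbours were chosen only after the result was seen, the one of embryo age with its value known. Preconditioned embryos differed from other N2 embryos on 500 mM against the direction of the salt response. The shared N2 500 mM libraries are argued against only weakly as the whole cause. The correlation with the salt response of lin-45, which shares no library, was -0.296, but its jackknife SE was 0.153. Low depth is argued against, since the most abundant genes gave -0.345. Younger preconditioned embryos stay open. Without N2 300-500 mM replicate 1, the library with more early zygotic transcripts, the correlation was -0.400, but this rests on a single preconditioned library and excludes nothing. A single deviant library stays open, since without replicate 2 the correlation was -0.190, short of the -0.2 set before the result was seen.

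A stage difference could lie in either preconditioned library, because early zygotic genes stood above N2 500 mM in replicate 1 and below it in replicate 2. Parental salt may lower the stress response of the offspring, as the lower DAF-16 and hypertonic lists in both libraries (-1.53 and -1.24, -1.27 and -0.93) and the correlation of -0.296 would allow. This is a hypothesis found and tested on the same data.

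A pair of neighbouring genes was nearly silent in the mutant libraries. irld-35 had 2837 counts in the 6 N2 libraries and 0 in the 4 lin-45 libraries, and F56A4.3 had 3450 and 2. On ce10 they lie on chromosome V at 2456174 to 2458285 and at 2453412 to 2456146, 28 bp apart. Neighbours kept counts in the mutant, with 329 and 152 for F56A4.10 and 716 and 717 for F56A4.5. F56A4.4 and str-267, between these genes, had counts identical to those of Y45G12C.3 and str-154 elsewhere on chromosome V, so their counts do not show which copy was expressed. On 50 and 500 mM, F56A4.4 was at -0.97 and -1.47 in the mutant and str-267 at -1.13 and -1.12, and F56A4.6 had 6 and 0 counts, so how far the silent stretch reaches stays open. All of these neighbours and copies but F56A4.5 were chosen after their values were seen. Linkage to lin-45 is argued against, since 0 of the 2 genes lie on chromosome IV. Chance neighbours stay open, since the 0.002% of random gene pairs that lay as close decides nothing, because the pair was singled out when it was seen to be adjacent. A deletion or other variant of this stretch in the lin-45 strain could give such counts, and DNA sequence, which would show it, was not analysed here.

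Other genes separated the strains at both salt levels. srw-85 stood at 0.855 to 2.26 CPM in N2 and 47.8 to 53.8 CPM in lin-45 libraries, and nhr-12 at 72.4 to 114 and 8.55 to 39.7 CPM. Of the 276 separating genes 7 differed at least 8-fold at both levels, 3 of them lower. Of these 7, srbc-15, F49H6.13 and F48C1.9 lie outside the naming rule and were chosen after their values were seen. If variants carried along with lin-45 set these differences, genes called in the same direction on both salt levels could cluster near lin-45. No clustering was seen, since 28 of 602 tested genes within 2 Mb of it (4.65%) and 706 of 14200 elsewhere (4.97%) were called (Fisher's exact test, two-sided, p = 0.848, odds ratio 0.932, 95% interval 0.609 to 1.374). The interval does not exclude a modest enrichment, and the 276 separating genes were not tested apart. By chromosome the share was highest on V, at 216 of 3154 (6.85%), where irld-35, F56A4.3, srw-85 and nhr-12 lie, and ranged from 3.71% to 5.53% on the other nuclear chromosomes. The cause of this difference was not tested.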
